A study of Homo sapiens with 24 samples.

How the data were processed

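Messenger RNA was profiled in 24 libraries of HEK293A cells, an adherent line derived from human embryonic kidney. The cells were grown in serum-containing medium on hydrogels coated with fibronectin, with a stiffness of 1 or 40 kPa. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a stranded poly(A) kit that came in index sets A and B. Which library got which set is not given in the sources used here, so no batch could be tested. The 8 groups of 3 biological replicates, as the series design text calls them, cross 4 genotypes with the 2 stiffnesses. The genotypes were wild type (WT) and lines labelled knockout for RAP2A, RAP2B and RAP2C (RAP2 tKO), for LATS1 and LATS2 (LATS dKO), and for YAP and TAZ (YAP/TAZ dKO). How the lines were edited, and how many clones stood behind each genotype, is not given in the sources used here. Genotypes are named as the labels give them.

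Per the submitters' processing notes, reads were processed with STAR 2.4.2a and Cufflinks 2.2.1 on the human genome build hg19. The annotation release, the strand setting and the treatment of reads with several matching places are not given in the sources used here. The authors deposited, per library, 1 table of gene FPKM values, which are fragment numbers as Cufflinks estimates them, divided by the length of the transcript and the depth of the library. Per the file headers, each table also holds a status and a confidence interval for each gene and its coordinates. Each table has 60350 entries under 58266 gene symbols, of which 338 stand on several entries and were summed. Left out were 92 symbols with an entry whose status was neither OK nor LOWDATA in some library. All 37 mitochondrial entries were listed at 0 in every library. Without a known strand setting, overlapping and antisense genes cannot be separated with certainty, and near-identical copies may share fragments.

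FPKM values hold no counts. The deposited confidence intervals of genes with few fragments still gave the depth, since their width follows the number of fragments. From 117 to 155 genes per library, the depth came to between 20.09 and 43.91 M fragments, a slight underestimate, with a median of 33.85 M. The FPKM of a library summed to between 829361 and 913869, and 13741 to 14418 genes per library had an FPKM of at least 1.

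The tests were run on log2(FPKM + 1), with no further scaling, on the 15828 genes with an FPKM of at least 1 in at least 3 libraries. Fold changes on this scale understate the change of genes with low FPKM. The limma package 3.58.1 in R 4.3.3 was fitted with 1 mean per group over all 24 libraries (16 residual degrees of freedom) and with a trend of the spread on the mean level, so that all groups share 1 estimate of the spread. The moderated test was two-sided, p-values were adjusted by the Benjamini-Hochberg method within each of 10 contrasts, and a gene was called where the adjusted p was below 0.05. The contrasts were 40 against 1 kPa in each of the 4 genotypes, the difference of that response between each knockout line and WT (the interaction), and each knockout line against WT as the mean of the differences at the 2 stiffnesses. Unless stated otherwise, a value written with ± is a mean FPKM with its SD over n = 3 libraries, and adjusted p-values of genes are limma's.

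Genes to be named followed a rule. For each stiffness and genotype contrast these were the 10 called genes with the largest rise and the 10 with the largest fall. The compared libraries had to be without overlap and the higher group at a mean FPKM of at least 5, leaving out short RNAs and clone names. For each interaction 5 in each direction were taken, without the condition on overlap. To these came the targeted genes, the YAP, TAZ and TEAD signature and up to 4 members of each called list with the smallest p. Some members of the lists are not reported here. Genes of 3 against 3 libraries that do not differ are without overlap in 10% of cases.

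Besides the targeted genes, taken 1 by 1, 27 gene lists were written down, and the 23 with at least 5 genes tested were set against all other genes with camera (preset correlation 0.01), adjusted over the lists within a contrast. They were the YAP, TAZ and TEAD signature, Hippo pathway genes, targets of SRF and its cofactor MRTF, immediate-early genes, matrix proteins, adhesion genes, cholesterol synthesis, fatty acid synthesis, hypoxia and glycolysis genes, genes of the ATF4 amino acid response, unfolded protein and heat shock genes, genes of G1/S and of G2/M, p53 targets, interferon response genes, targets of TGF-beta, of Wnt and of Notch, ribosomal proteins, oxidative phosphorylation, histones, and epithelial and fibroblast markers. Neuronal, immune and endothelial markers and the mitochondrial genome had too few genes tested. Camera was rerun with a correlation estimated from the data, and 27 of the 78 list calls held. Fry, also run in its directional form, tests a list for a change in a common direction, not against other genes. A list that fry did not call may still hold changes in both directions.

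A stiffness response score was computed per library as the mean over the genes called in WT of log2(FPKM + 1), counted negative for genes lower at 40 kPa. It was compared within each knockout line by an exact two-sided permutation test of 3 against 3 libraries, whose smallest possible p is 0.1. Stiffness calls shared by WT and a knockout line were set against the number that independent lists would share, with a one-sided hypergeometric test per direction. The stiffness contrasts use separate libraries and share no controls, but they share 1 estimate of the spread per gene.

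The groups, contrasts, tests, gene lists, the rule for named genes and a first set of alternatives were fixed before the data were examined. These alternatives were another pseudocount (0.1), no filter, a stricter filter (FPKM of at least 5), libraries scaled to a common median ratio, a fit of the compared groups alone, the replicate number as a block, limma array weights and the fit without each library. Alternatives that need counts were not run, since the files hold FPKM. Added after seeing the data were fits without the 2 libraries that deviate with GC content, a GC correction per library, and these and further alternatives for the score and the shared calls. The GC content came from the transcripts of GENCODE 29, matched to 15511 of the genes tested (98%). The correction removed the median deviation from the gene's mean in 50 bins of GC content. In some alternative fits limma met genes with a sample variance of 0 and offset them.

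The fit was tested on simulated data of the same 15828 genes, 200 of them changed. For stiffness in WT it recovered 55.2% of genes changed by 0.5 on the log2 scale, 89.6% by 1 and 89.4% by 2, and called 11 unchanged genes. For the interactions it recovered 35.8% (RAP2 tKO), 37.3% (LATS dKO) and 22.4% (YAP/TAZ dKO) of genes changed by 0.5, so an interaction of that size is often missed. Camera called the shifted list in 20 of 20 rounds and 1 of 400 unshifted lists. The simulated genes varied independently, so these rounds give no error rate for lists whose genes vary together. Among the real lists the estimated correlation was 0.441 for G2/M genes and 0.634 for Notch targets. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.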

Results

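The series asks how gene expression in HEK293A cells responds to the stiffness of the matrix they grow on, and what the small GTPases RAP2A, RAP2B and RAP2C and the Hippo pathway have to do with that response. In the Hippo pathway the kinases LATS1 and LATS2 restrain the coactivators YAP and TAZ (gene WWTR1), which act through TEAD transcription factors. Gene FPKM values of 24 libraries were compared, 3 for each of WT, RAP2 tKO, LATS dKO and YAP/TAZ dKO cells on soft (1 kPa) and stiff (40 kPa) hydrogels. The libraries held 20.09 to 43.91 M fragments, so that the smallest, LATS dKO on 40 kPa replicate 1, was also the least precise by depth. The SD of the log2 difference between pairs of replicates lay between 0.397 and 0.71. Of the 24 libraries, RAP2 tKO on 40 kPa replicate 3 and LATS dKO on 40 kPa replicate 1 deviated from their groups with the GC content of the genes (rank correlation across genes -0.60 and -0.57, genes not being independent). In the 18 libraries of the other 6 groups the largest such correlation was 0.33 in size. The remaining replicates of both groups had correlations of the opposite sign (0.536 and 0.486 in RAP2 tKO, 0.468 and 0.382 in LATS dKO), which centring on a mean of 3 ties to those of the named libraries. For the change from the 1 kPa mean of the same genotype, which holds none of these 6 libraries, the correlation was -0.593 and -0.57 in the named libraries and -0.09 to 0.153 in the remaining replicates. Each count of called genes is therefore given also without both libraries.

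**Figure D1:**
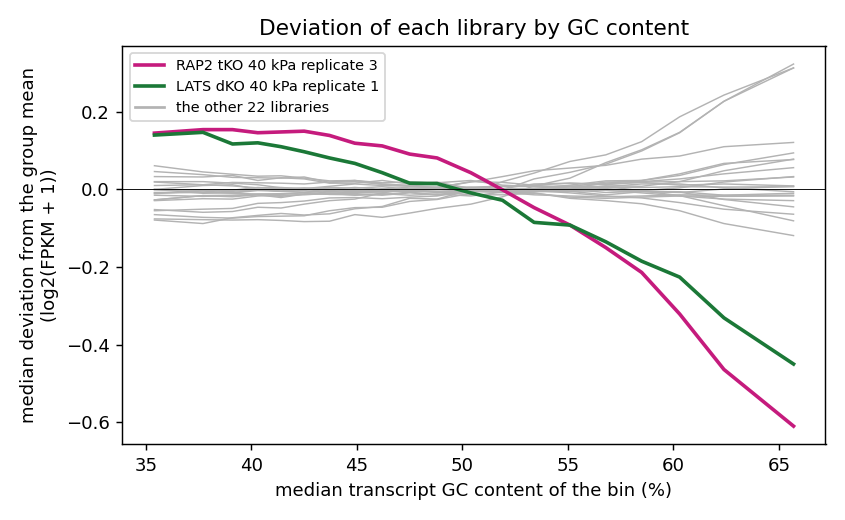
Median deviation of each library from its group mean (log2 FPKM + 1) against the median transcript GC content (percent) of 20 bins of genes, 1 line per library. RAP2 tKO on 40 kPa replicate 3 (rank correlation -0.60) and LATS dKO on 40 kPa replicate 1 (-0.57) are coloured and the other 22 libraries are grey.

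The targeted genes were measured first, all positions being hg19. In YAP/TAZ dKO cells YAP1 (ENSG00000137693.13, chromosome 11, 101981192 to 102104154) fell from 30.9 ± 1.05 to 6.06 ± 0.178 FPKM on 1 kPa and from 31.6 ± 0.614 to 6.20 ± 0.653 on 40 kPa (log2 change -2.18, adjusted p = 1.37e-16). WWTR1 (ENSG00000018408.14, chromosome 3, 149235022 to 149454501) fell from 27.3 ± 3 to 10.0 ± 1.12 and from 26.3 ± 0.685 to 10.7 ± 0.724 FPKM (-1.29, adjusted p = 7.03e-11), in a chromosome window whose genes had a median of -0.82 in that line. In LATS dKO cells LATS1 (ENSG00000131023.12, chromosome 6, 149979289 to 150039392) fell from 12.9 ± 1.03 to 5.18 ± 0.307 and from 12.3 ± 0.156 to 5.69 ± 0.299 FPKM (-1.08, adjusted p = 2.05e-11). LATS2 (ENSG00000150457.8, chromosome 13, 21547171 to 21635686) was not called there, at 3.19 ± 0.228 and 3.40 ± 0.791 FPKM against 2.16 ± 0.358 and 2.78 ± 0.738 in WT (0.32, adjusted p = 0.091). In the libraries labelled RAP2 tKO, RAP2A (ENSG00000125249.6, chromosome 13, 98086476 to 98121382) fell from 7.92 ± 0.16 to 6.36 ± 0.868 and from 8.78 ± 0.245 to 6.79 ± 0.667 FPKM (-0.31, adjusted p = 0.00397). RAP2B (ENSG00000181467.3, chromosome 3, 152880059 to 152884962) rose (0.26, adjusted p = 0.00084), and RAP2C (ENSG00000123728.9, chromosome X, 131337052 to 131353508) was not called (0.17, adjusted p = 0.238). RNA of a gene disrupted by a small edit can persist, so the levels of RAP2B, RAP2C and LATS2 do not check the labels of these lines. Keratins, ribosomal proteins, HSPA1A, the IFITM genes, GOLGA8A, GTF2I and SBDSP1 have near-identical copies and CHURC1-FNTB overlaps its parent genes, so their levels are uncertain to that extent.

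The first comparison asked which genes respond to stiffness in WT cells. The secreted matricellular proteins CTGF (ENSG00000118523.5, chromosome 6, 132269316 to 132272513) and CYR61 (ENSG00000142871.15, chromosome 1, 86046444 to 86049645), both classic targets of YAP and TAZ, were higher on the stiff gel. CTGF rose from 6.55 ± 0.367 to 22.5 ± 0.88 FPKM (log2 change 1.64, adjusted p = 7.24e-13) and CYR61 from 14.8 ± 0.932 to 30.5 ± 2.19 (0.99, adjusted p = 3.25e-06). ANKRD1 (ENSG00000148677.6, chromosome 10, 92671853 to 92681033), a muscle ankyrin repeat protein and another target, rose from 0.877 ± 0.239 to 4.02 ± 0.0673 FPKM (1.43, adjusted p = 1.03e-07). AMOTL2 (ENSG00000114019.14, chromosome 3, 134074716 to 134094321), an angiomotin that binds YAP, rose from 9.18 ± 1.71 to 25.4 ± 1.98 FPKM (1.39, adjusted p = 0.000979). DDIT4, an inhibitor of mTORC1 signalling, fell from 10.3 ± 1.11 to 4.81 ± 0.294 FPKM (-0.95, adjusted p = 0.000161).

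Of the other genes with the largest rise in WT, AJUBA, a LIM protein that binds LATS kinases, went from 6.90 ± 0.535 to 15.7 ± 1.67 FPKM, and the keratins KRT8 and KRT18 from 141.1 ± 5.97 to 236.5 ± 5.98 and from 143.9 ± 8.04 to 234.5 ± 8.28. SMAD7, an inhibitor of TGF-beta signalling, rose from 18.6 ± 1.86 to 29.4 ± 2.34 FPKM. The clathrin adaptor subunit AP1M2, the matrix glycoprotein EMILIN2 and the receptor GPRC5A rose by 0.72, 0.69 and 0.68 on the log2 scale. Among the genes that fell were DDB2, a DNA damage binding protein (48.8 ± 4.04 to 31.5 ± 2.93 FPKM), the nuclear noncoding RNA NEAT1 (177.4 ± 7.61 to 118.2 ± 5.87), the linker histone H1F0 (31.7 ± 0.184 to 20.9 ± 0.309) and asparagine synthetase ASNS (103.8 ± 7.69 to 71.2 ± 2.58). ANK2, DHRS3, SEC31B, ACCS and ACSF2 completed the list of falls, with log2 changes between -0.67 and -0.54.

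Of the 20 members of the YAP, TAZ and TEAD signature tested, 4 rose in WT, 0 fell and 16 were not called, and 5 rose and 2 fell when adjusted over the list alone (camera adjusted p = 7.76e-07). The 6 epithelial markers tested held 2 that rose, KRT8 and KRT18, and when adjusted over the list alone also 1 that fell, CLDN7 (-0.45; camera adjusted p = 4.67e-05). Of 25 genes of the ATF4 amino acid response, which serve amino acid supply under stress, 4 fell (DDIT4, ASNS, DDIT3 and NUPR1) and 21 were not called, with 9 falling and 2 rising when adjusted over the list alone (camera adjusted p = 3.21e-05). These 3 lists held with an estimated correlation. Mitosis genes of G2/M were placed higher with 1 of 24 called, CDCA8 (camera adjusted p = 0.00195, but adjusted p = 0.426 with an estimated correlation). Of 18 unfolded protein and heat shock genes the chaperones HSPA5 and PDIA4 rose, with 2 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0391, and adjusted p = 0.0695 with an estimated correlation). Of 11 TGF-beta targets SMAD7 rose, the list having adjusted p = 0.0491 and, with an estimated correlation, adjusted p = 0.185. Adhesion genes (adjusted p = 0.0116), cholesterol synthesis (camera adjusted p = 0.0116) and Hippo pathway genes (camera adjusted p = 0.0475) were placed higher and interferon response genes (camera adjusted p = 0.0495) lower with 0 members called. With an estimated correlation their adjusted p-values were 0.0676, 0.185, 0.185 and 0.105. Adjusted over the list alone, 2 Hippo genes rose and 2 interferon genes fell. The call of interferon response genes was lost without both GC-skewed libraries, and that of TGF-beta targets with GC correction, with scaling and without a filter. Those of both these lists, of Hippo genes and of the unfolded protein list were lost with a pseudocount of 0.1, and that of Hippo genes also without a filter.

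In all, 156 of 15828 genes were called for stiffness in WT (limma), 51 higher and 105 lower, and 6 by at least 2-fold. Without both GC-skewed libraries, which changes the shared spread and no WT library, there were 1006 calls (368 higher, 638 lower), among them all 156. The balance of directions followed the scaling, with 127 higher and 75 lower of 202 once libraries were scaled to a common median ratio and 250 higher and 189 lower of 439 after GC correction. Leaving out 1 of the 6 WT libraries gave 46 to 104 calls and fitting these 6 alone gave 45. The calls of CTGF, AMOTL2, AJUBA, CYR61, KRT8, KRT18, DDIT4, NEAT1, H1F0 and ANKRD1 held in every setting tried, 10 of the 26 named.

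**Figure D2:**
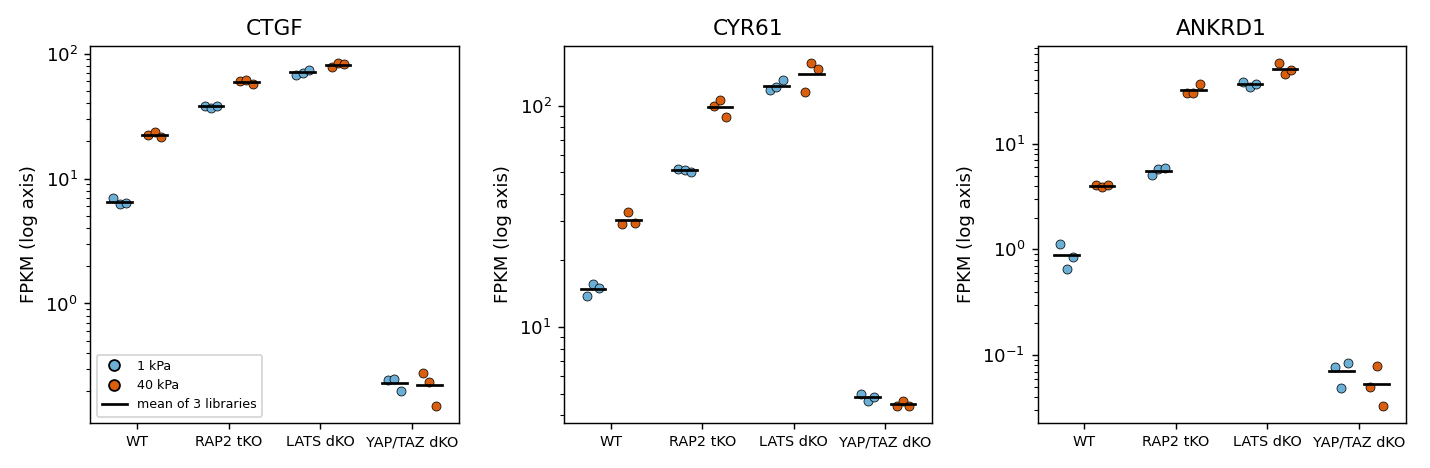
FPKM of CTGF, CYR61 and ANKRD1 on a log axis, 1 point per library and a bar at the mean of 3, on 1 kPa (blue) and 40 kPa (orange) in the 4 genotypes. The ratio of the 40 kPa mean to the 1 kPa mean of CTGF is 3.44 in WT, 1.58 in RAP2 tKO, 1.15 in LATS dKO and 0.962 in YAP/TAZ dKO.

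In the libraries labelled RAP2 tKO, ANKRD1 rose with stiffness from 5.57 ± 0.443 to 32.4 ± 3.74 FPKM (log2 change 2.34, adjusted p = 4.06e-11). CYR61 rose from 51.1 ± 0.846 to 98.3 ± 8.38 FPKM (0.93, adjusted p = 4.69e-06). CTGF rose from 37.8 ± 0.716 to 59.7 ± 2.38 (0.65, adjusted p = 8.95e-07). AMOTL2 stood at 43.1 ± 3.51 and 59.8 ± 17.4 FPKM and was not called (0.42, adjusted p = 0.215). The stress transcription factor ATF3 went from 32.9 ± 2.31 to 58.1 ± 9 FPKM. The secreted glycoprotein FSTL1 went from 81.9 ± 2.71 to 140.9 ± 14.8. The immediate-early genes EGR1 and FOS, which answer to growth factors, fell, EGR1 going from 9.38 ± 0.745 to 1.72 ± 0.297 FPKM (-1.94, adjusted p = 1.69e-07) and FOS from 7.28 ± 1.1 to 1.18 ± 0.738 (-1.97, adjusted p = 0.000297). DDIT4 fell from 12.1 ± 1.25 to 3.35 ± 0.72 FPKM (-1.60, adjusted p = 8.88e-08).

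The other genes named for their rise in RAP2 tKO were UBE2QL1 (1.14), EMILIN2 (1.01), CHURC1-FNTB (0.99), AP1M2 (0.89), WFDC21P (0.81) and RBM47 (0.77). Those named for their fall were FOSB (-1.78), CRIP2 (-1.62), JUNB (-1.56), NR4A1 (-1.15), CTD-2228K2.7 (-1.14), ICAM5 (-1.13) and MAPK15 (-1.11), all on the log2 scale. The calls of FOSB, CRIP2, JUNB, ICAM5, CTD-2228K2.7, CHURC1-FNTB and RBM47 were lost without RAP2 tKO on 40 kPa replicate 3. So were those of the list members TGFB2, CDKN1A, IFITM1, BST2, HEY1, HEY2 and RPLP0.

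Of 25 ATF4 response genes 13 fell in RAP2 tKO and 12 were not called, with 18 falling when adjusted over the list alone (camera adjusted p = 1.53e-10); CHAC1, DDIT3 and NUPR1 were among them. Of 20 signature members 4 rose (ANKRD1, CYR61, CTGF and TGFB2) and FOXF2 fell, with 6 and 1 when adjusted over the list alone (camera adjusted p = 9.32e-06). FOXF2 fell by 0.30 but stood at 0.04 after GC correction. Interferon response genes were placed lower, with IFITM1 and BST2 fallen of 17 and 5 when adjusted over the list alone (camera adjusted p = 0.00266). These 3 lists held with an estimated correlation. Of 23 immediate-early genes 10 fell and 2 rose (14 and 3 when adjusted over the list alone), KLF10 falling and ATF3 rising (camera adjusted p = 1.37e-06, but adjusted p = 0.17 with an estimated correlation). Of 24 cholesterol synthesis genes 4 fell, INSIG1 (51.6 ± 3.74 to 34.3 ± 4.01 FPKM), IDI1, HMGCS1 and TM7SF2 (7 when adjusted over the list alone; camera adjusted p = 0.00569, and adjusted p = 0.17 with an estimated correlation).

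The other lists called in RAP2 tKO lost the call with an estimated correlation. Notch targets were placed lower, with HEY1 and HEY2 fallen of 8 and 6 when adjusted over the list alone (camera adjusted p = 0.000296, and adjusted p = 0.208 with an estimated correlation). Of 32 ribosomal proteins RPLP0 fell, and 3 when adjusted over the list alone (camera adjusted p = 0.0018, and adjusted p = 0.249 with an estimated correlation). Of 17 p53 targets CDKN1A fell, and 4 when adjusted over the list alone (camera adjusted p = 0.0297, and adjusted p = 0.095 with an estimated correlation). CDCA8 rose of 24 G2/M genes (camera adjusted p = 0.00284, and adjusted p = 0.344 with an estimated correlation), and without both GC-skewed libraries that list had adjusted p = 0.548. Of 35 adhesion genes, placed higher, 0 were called (camera adjusted p = 0.0199, and adjusted p = 0.104 with an estimated correlation), a call also lost without a filter.

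In RAP2 tKO 612 genes were called for stiffness, 156 higher and 456 lower, and 30 by at least 2-fold. Leaving out both GC-skewed libraries gave 795 calls (208 higher, 587 lower), 460 of them among the 612. Scaled to a common median ratio the split was 374 higher and 311 lower, and after GC correction 531 and 437. Leaving out 1 of the 6 RAP2 tKO libraries gave 258 to 1141 calls and fitting these 6 alone gave 8. Of 38 named genes the calls of ANKRD1 and EGR1 held in every setting.

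In LATS dKO cells ANKRD1 rose with stiffness from 36.6 ± 2.19 to 51.2 ± 6.25 FPKM (log2 change 0.47, adjusted p = 0.035) and EMILIN2 from 5.20 ± 0.241 to 8.97 ± 1.73 (0.67, adjusted p = 0.0213). CTGF was at 70.7 ± 3.09 and 81.6 ± 3.35 FPKM (0.21, adjusted p = 0.0899), CYR61 at 123 ± 6.43 and 138.8 ± 21.2 (0.16, adjusted p = 0.464) and AMOTL2 at 65.5 ± 2.42 and 68.6 ± 16.2 (0.04, adjusted p = 0.967), none of them called. The membrane protein EMP3 fell from 94.4 ± 2.49 to 53.4 ± 5.25 FPKM (-0.81, adjusted p = 0.00388), and the transcription factor NFATC4 from 15.0 ± 0.589 to 9.26 ± 0.339. RRM2, a subunit of ribonucleotide reductase, rose from 129.3 ± 15.6 to 165.2 ± 11.1 FPKM.

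RNF138, SBDSP1, GTF2I, MARCKS, SEC16A and DNAJC9 were also named for a rise in LATS dKO, between 0.36 and 0.16 on the log2 scale, and CCDC78, RBM47, CCBL1, ENO2, NMU, PCGF1, TNFAIP2 and HSD17B8 for a fall, between -0.96 and -0.51. Of 20 signature members ANKRD1 rose and the list was not called (camera adjusted p = 0.211), but it was without both GC-skewed libraries (adjusted p = 0.0251, the lowest of a range up to 0.46 over the alternatives). Of 32 ribosomal proteins 4 fell, RPS3, RPL10 and RPL37 among them, and 16 fell when adjusted over the list alone (camera adjusted p = 2.49e-08, but adjusted p = 0.0976 with an estimated correlation). The 25 ATF4 response genes were placed lower with 0 called, 1 when adjusted over the list alone (camera adjusted p = 0.000651, and adjusted p = 0.0976 with an estimated correlation). The 11 TGF-beta targets were placed higher with 0 called and 2 when adjusted over the list alone (camera adjusted p = 0.00226, and adjusted p = 0.0976 with an estimated correlation). Of 25 SRF and MRTF targets TPM2 fell, with 6 when adjusted over the list alone (camera adjusted p = 0.0122, and adjusted p = 0.0976 with an estimated correlation). Of 23 immediate-early genes 0 were called and 4 fell when adjusted over the list alone (camera adjusted p = 0.00906, and adjusted p = 0.494 with an estimated correlation). Without both GC-skewed libraries the last pair of lists had adjusted p = 0.362 and 0.799, and both calls were also lost with GC correction.

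In LATS dKO 112 genes were called for stiffness, 14 higher and 98 lower, and 2 by at least 2-fold. In the fit without both GC-skewed libraries 472 were called (186 higher, 286 lower), 95 of them shared with the 112. Scaled to a common median ratio there were 15 higher and 34 lower, and after GC correction 39 and 42. Leaving out 1 of the 6 LATS dKO libraries gave 17 to 255 calls and fitting these 6 alone gave 2. Of 24 named genes 0 kept the call in every setting.

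In YAP/TAZ dKO cells CTGF, CYR61, ANKRD1 and AMOTL2 were not called for stiffness, with log2 changes of -0.01, -0.08, -0.02 and -0.28 (adjusted p = 0.99, 0.894, 0.986 and 0.819). The immediate-early transcription factors FOSB and FOS fell, from 13.3 ± 1.95 to 1.45 ± 0.489 FPKM (-2.56, adjusted p = 0.00149) and from 5.25 ± 0.982 to 0.632 ± 0.0444 (-1.93, adjusted p = 0.00109). EMP3 fell from 96.0 ± 4.67 to 38.6 ± 6.61 FPKM (-1.31, adjusted p = 9.05e-07). The secreted chaperone CLU fell from 341.9 ± 17.3 to 235.5 ± 19.4 (-0.54, adjusted p = 8.01e-05). IGFBP5, which binds insulin-like growth factors, rose from 6.98 ± 0.361 to 10.4 ± 0.841 FPKM (0.51, adjusted p = 0.0186). DDB2, which fell in WT, rose from 19.9 ± 1.85 to 27.8 ± 2.45 (0.46, adjusted p = 0.0355).

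GOLGA8A, LY6G5B, STAT2, PCDH9, HES5, ZNF527, HNRNPH1 and CHKB were further named for a rise in YAP/TAZ dKO, between 0.51 and 0.37 on the log2 scale, and MYADM, GNG4, PPP1R15A, TSC22D3, S100A10 and SLC43A1 for a fall, between -1.15 and -0.48. The 20 signature members held 0 called, and the list was not called (camera adjusted p = 0.127). Of 23 immediate-early genes 5 fell, FOS, FOSB, EGR3 and EGR1 among them, and 12 when adjusted over the list alone (camera adjusted p = 2.48e-16). Of 25 ATF4 response genes ATF4 itself fell, from 278.8 ± 4.22 to 228.8 ± 2.92 FPKM, and 9 when adjusted over the list alone (camera adjusted p = 2.75e-12). Of 25 SRF and MRTF targets TAGLN2 and TGFB1I1 fell, and 4 when adjusted over the list alone (camera adjusted p = 6.9e-05). The 11 TGF-beta targets were placed higher with 0 called and 3 when adjusted over the list alone (camera adjusted p = 0.000285). These 4 lists held with an estimated correlation. CD44, the hyaluronan receptor, fell from 3.83 ± 0.619 to 1.48 ± 0.453 FPKM, the 1 called of 35 adhesion genes (3 when adjusted over the list alone; camera adjusted p = 0.0357, and adjusted p = 0.117 with an estimated correlation). Ribosomal proteins (camera adjusted p = 0.000313) and histones (camera adjusted p = 0.0179) were placed lower and cholesterol synthesis (camera adjusted p = 0.000968) higher with 0 called, and with an estimated correlation their adjusted p-values were 0.291, 0.323 and 0.117. Adjusted over the list alone, 1 cholesterol synthesis gene rose.

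In YAP/TAZ dKO 55 genes were called for stiffness, 19 higher and 36 lower, and 9 by at least 2-fold. With both GC-skewed libraries left out, which are not of this line, 391 were called (131 higher, 260 lower), among them all 55; the adhesion genes and the histones then had adjusted p = 0.155 each. Leaving out 1 of the 6 YAP/TAZ dKO libraries gave 29 to 43 calls. Of 26 named genes the calls of GOLGA8A, FOSB, FOS, EMP3, PPP1R15A, S100A10 and TAGLN2 held in every setting.

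Next, the response to stiffness was compared with that of WT on the log2 scale. In RAP2 tKO the rise of CTGF was smaller than in WT, though not in FPKM (interaction -0.99, adjusted p = 1.61e-06). That of KRT18, at 265 ± 2.7 and 272.9 ± 23.7 FPKM in RAP2 tKO, was smaller too (-0.66, adjusted p = 0.00269). EGR1 fell in RAP2 tKO and stood at 3.57 ± 0.27 and 3.06 ± 0.82 FPKM in WT (-1.75, adjusted p = 0.000597). ETV4, an ETS transcription factor, went from 18.6 ± 0.9 to 10.8 ± 1.67 FPKM against 10.3 ± 0.826 and 14.8 ± 0.952 in WT (-1.22, adjusted p = 0.00797). NAB2, a corepressor of EGR1, went from 14.4 ± 0.412 to 7.01 ± 1.43 (-0.81, adjusted p = 0.0325). ANKRD1 (0.92, adjusted p = 0.00797) and FSTL1 (0.55, adjusted p = 0.0325) rose more than in WT. The interaction of ANKRD1, whose WT level on 1 kPa is below 1 FPKM, came to 0.41 with a pseudocount of 0.1 (adjusted p = 0.751).

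Called in the RAP2 tKO interaction were 8 genes, 2 higher and 6 lower, and 20 without both GC-skewed libraries (5 higher, 15 lower), among them all 8. With a pseudocount of 0.1 there were 3 calls, those of FSTL1, NAB2 and ETV4 being lost with that of ANKRD1, while EGR1 and CTGF held in every setting. Signature members were called in both directions, 1 higher and 1 lower of 20 (camera adjusted p = 0.994). Cholesterol synthesis genes (camera adjusted p = 3.13e-07) and ATF4 response genes (camera adjusted p = 0.000154) were placed lower with 0 called, 5 and 1 when adjusted over the list alone, and held with an estimated correlation. Immediate-early genes (camera adjusted p = 1.31e-05; EGR1 called of 23, 8 lower and 3 higher when adjusted over the list alone), ribosomal proteins (camera adjusted p = 0.00215), Notch targets (camera adjusted p = 0.0241) and epithelial markers (camera adjusted p = 0.0241; KRT18 called of 6, 2 when adjusted over the list alone) were placed lower too. With an estimated correlation these 4 lists had adjusted p = 0.321, 0.459, 0.492 and 0.0984. Notch targets had adjusted p = 0.27 without both GC-skewed libraries, and the calls of Notch targets and epithelial markers were lost with GC correction.

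In LATS dKO the stiffness response was smaller than in WT for CTGF (interaction -1.44, adjusted p = 3.25e-09), ANKRD1 (-0.96, adjusted p = 0.00447), CYR61 (-0.83, adjusted p = 0.0069), AJUBA (-1.17, adjusted p = 0.0069), KRT18 (-0.86, adjusted p = 9.39e-05) and KRT8 (-0.64, adjusted p = 0.00447). AJUBA stood at 67.9 ± 2.77 and 63.9 ± 8.12 FPKM in LATS dKO and KRT18 at 439.8 ± 12 and 395.2 ± 23.1. In FPKM ANKRD1 rose by more than in WT, CYR61 about as much and CTGF less. PDE7A, a phosphodiesterase that degrades cyclic AMP, fell from 16.03 ± 0.542 to 13.2 ± 0.136 FPKM in WT and went from 13.9 ± 0.568 to 16.2 ± 1.13 in LATS dKO (0.47, adjusted p = 0.0343).

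Called in the LATS dKO interaction were 10 genes, 3 higher and 7 lower, against 211 without both GC-skewed libraries (77 higher, 134 lower), among them all 10. The split was 3 higher and 17 lower once scaled, and 16 and 22 after GC correction. Of the 7 named genes CTGF, AJUBA and KRT18 held in every setting. The signature was placed lower, with 3 of 20 called and 5 when adjusted over the list alone (camera adjusted p = 0.000162), as were epithelial markers (2 of 6; camera adjusted p = 3.21e-05) and SRF and MRTF targets (0 of 25, 4 when adjusted over the list alone; camera adjusted p = 0.000529), all 3 holding with an estimated correlation. Ribosomal proteins (camera adjusted p = 2.1e-05; 4 when adjusted over the list alone) and adhesion genes (camera adjusted p = 0.0111) were placed lower and p53 targets (camera adjusted p = 0.0472; 3 higher and 1 lower when adjusted over the list alone) higher with 0 called. With an estimated correlation they had adjusted p = 0.157, 0.0627 and 0.0732, and adhesion genes had 0.0519 without both GC-skewed libraries.

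In YAP/TAZ dKO the responses of AMOTL2 (interaction -1.66, adjusted p = 0.00717), CTGF (-1.65, adjusted p = 2.85e-10), ANKRD1 (-1.45, adjusted p = 1.13e-05), CYR61 (-1.08, adjusted p = 0.000128), KRT8 (-0.95, adjusted p = 1.4e-05) and KRT18 (-0.86, adjusted p = 2.81e-05) were below those of WT. ANXA1 went from 3.54 ± 0.392 to 0.667 ± 0.0621 FPKM in YAP/TAZ dKO and stood at 25.2 ± 2.14 and 25.2 ± 0.67 in WT (-1.44, adjusted p = 5.69e-06). TNFRSF12A had -1.09 (adjusted p = 0.0458) and TAGLN2 -0.47 (adjusted p = 0.00798). Responses were above WT for IGFBP5 (1.09), DDB2 (1.08), SEC31B (0.98), DDIT4 (0.80), STAT2 (0.74) and HES5 (0.71), with adjusted p between 0.000293 and 0.0269.

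Called in the YAP/TAZ dKO interaction were 62 genes, 41 higher and 21 lower. Leaving out both GC-skewed libraries gave 413 (216 higher, 197 lower), among them all 62, while scaling gave 38 higher and 36 lower and GC correction 71 and 77. The calls of DDIT4, TNFRSF12A and HES5 were lost in some setting and those of the other 12 named genes in none. The signature was placed lower (4 of 20 called, also when adjusted over the list alone; camera adjusted p = 1.55e-08), as were SRF and MRTF targets (1 of 25, TAGLN2, with 4 lower and 2 higher when adjusted over the list alone; camera adjusted p = 5.26e-06), epithelial markers (2 of 6; camera adjusted p = 0.000119) and adhesion genes (0 of 35, 2 when adjusted over the list alone; camera adjusted p = 0.000119), and these 4 held with an estimated correlation. Immediate-early genes (camera adjusted p = 5.22e-07; 8 lower and 1 higher when adjusted over the list alone), G2/M genes (camera adjusted p = 0.0146) and ribosomal proteins (camera adjusted p = 0.0201) were placed lower and p53 targets (camera adjusted p = 0.0418; 1 when adjusted over the list alone) higher with 0 called, as were Notch targets with HES5 called (camera adjusted p = 0.0483). With an estimated correlation these 5 had adjusted p = 0.17, 0.453, 0.453, 0.0834 and 0.453. The call of Notch targets was also lost without a filter and with a pseudocount of 0.1.

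A further comparison asked how much of the WT response each knockout line showed. Over the 156 genes called in WT the stiffness response score differed between 40 and 1 kPa by 0.46 ± 0.019 in WT, where the genes were chosen, by 0.35 ± 0.022 in RAP2 tKO, 0.13 ± 0.011 in LATS dKO and 0.03 ± 0.024 in YAP/TAZ dKO, or 74.9%, 27.5% and 7.1% of the WT difference (n = 3 per group). In each knockout line every library on 40 kPa was at or above every library on 1 kPa, and the exact two-sided permutation p was 0.1 each (adjusted 0.1), the smallest that 3 against 3 libraries allow. The choice of genes favours the WT difference. Over the 45 genes called in a fit of the compared groups alone, 21 of them among the 156, the difference was 1.43 in WT, 0.45 in RAP2 tKO, 0.34 in LATS dKO and -0.02 in YAP/TAZ dKO, or 31.7%, 23.8% and -1.7% of that in WT. Over the 1006 genes called in WT without both GC-skewed libraries it was 0.32, 0.22, 0.08 and 0.04, or 68.4%, 25.6% and 12.2%.

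Of the 51 genes that rose in WT, 26 such as CTGF and CYR61 were also called higher in RAP2 tKO, where independent lists would share 0.503 (one-sided exact hypergeometric p = 1.56e-39, adjusted over 6 tests 4.68e-39). Of the 105 that fell 61 such as DDIT4 were also called lower, against 3.03 (exact p = 4.82e-67, adjusted 2.89e-66). LATS dKO shared 2 higher calls (0.0451 for independent lists, exact p = 0.000904, adjusted 0.00108) and 16 lower (0.65, p = 2.61e-18, adjusted 5.22e-18). YAP/TAZ dKO shared 0 higher (0.0612, exact p = 1, adjusted 1) and 6 lower (0.239, p = 1.22e-07, adjusted 1.83e-07). Genes are not independent, so these p-values are too small. The shared calls numbered 2 in RAP2 tKO, 1 in LATS dKO and 1 in YAP/TAZ dKO with the compared groups fitted alone, and 338, 85 and 54 without both GC-skewed libraries. Of the WT genes that rose, 98% had the same sign in RAP2 tKO, 64.7% in LATS dKO and 49% in YAP/TAZ dKO, and of those that fell 97.1%, 83.8% and 58.1%. On the log2 scale the interaction test called a smaller response for 2 of the 51 and 0 of the 105 in RAP2 tKO, for 7 and 3 in LATS dKO and for 13 and 27 in YAP/TAZ dKO. It called a larger response for 1 of the 51 and 0 of the 105 in RAP2 tKO, for 0 and 0 in LATS dKO and for 0 and 1 in YAP/TAZ dKO.

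**Figure D3:**
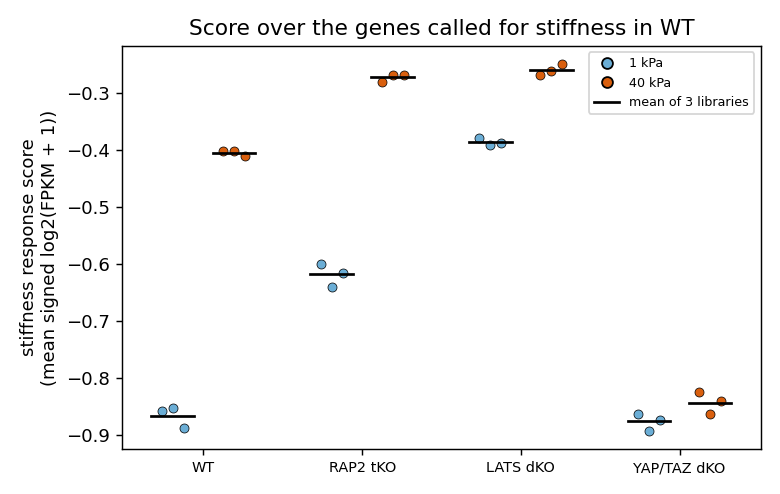
Stiffness response score (mean of log2(FPKM + 1) over the 156 genes called in WT, counted negative for genes that fall) per library on 1 and 40 kPa in the 4 genotypes. The group means go from -0.87 to -0.40 in WT, from -0.62 to -0.27 in RAP2 tKO, from -0.39 to -0.26 in LATS dKO and from -0.88 to -0.84 in YAP/TAZ dKO.

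The last comparison set each knockout line against WT over both stiffnesses. In the libraries labelled RAP2 tKO, ANKRD1 was higher by 2.27 on the log2 scale (adjusted p = 7.67e-14), CTGF by 1.86 (adjusted p = 1.52e-16), CYR61 by 1.69 (adjusted p = 1.08e-12) and AMOTL2 by 1.65 (adjusted p = 9.89e-08). BST2, an interferon-induced membrane protein also called tetherin, rose from 62.0 ± 2.96 to 177.2 ± 3.55 on 1 kPa and from 52.0 ± 1.97 to 144.9 ± 8.44 FPKM on 40 kPa. Lower were PALM, a membrane-anchored phosphoprotein (87.6 ± 9.71 to 15.98 ± 1.86 FPKM on 1 kPa; -2.84, adjusted p = 1.46e-07), RAMP1, a partner of calcitonin-like receptors (11.7 ± 1.59 to 1.17 ± 0.0812; -2.62), and VAMP8, a vesicle fusion protein (21.7 ± 2.18 to 4.04 ± 0.278; -2.24). AJUBA, LBH, FSTL1, GPRC5A and TNFRSF12A were further named as higher (1.29 to 1.00) and CGA, RGS3, COL14A1, P2RY11, PLPPR3, ALG1L and TMEM216 as lower (-1.73 to -0.99).

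Of 20 signature members 14 were higher in RAP2 tKO, 0 lower and 6 not called, also when adjusted over the list alone (camera adjusted p = 7.29e-14). Of 25 SRF and MRTF targets 7 were higher, among them TPM1, VCL, CNN2 and CSRP1, and 1 lower (10 and 1 when adjusted over the list alone; camera adjusted p = 0.000414). Both lists held with an estimated correlation, and the following did not. Of 32 ribosomal proteins 9 were lower, also when adjusted over the list alone, RPS6, RPL35 and RPS14 among them (camera adjusted p = 1.79e-05, and adjusted p = 0.2 with an estimated correlation). Of 23 immediate-early genes 8 were higher, such as ATF3 and DUSP1, and 4 lower (10 and 4 when adjusted over the list alone; camera adjusted p = 0.0047, and adjusted p = 0.384 with an estimated correlation). Of 35 adhesion genes 9 were higher, such as CD44 and ITGB8, and 3 lower, such as the integrin linker TLN1 (11 and 4 when adjusted over the list alone; camera adjusted p = 0.0207, and adjusted p = 0.0914 with an estimated correlation). Of 18 unfolded protein and heat shock genes 7 were lower and 1 higher, also when adjusted over the list alone, HSPA1A going from 2.82 ± 0.277 to 0.128 ± 0.0755 FPKM on 1 kPa, beside HSPA5, PDIA4 and XBP1 (camera adjusted p = 0.0299, and adjusted p = 0.0839 with an estimated correlation). Of 8 Notch targets HEY1, HES5 and NOTCH3 were lower, also when adjusted over the list alone (camera adjusted p = 0.0421, and adjusted p = 0.506 with an estimated correlation), the list having adjusted p = 0.277 without both GC-skewed libraries and losing the call with GC correction too.

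For RAP2 tKO against WT 2528 genes were called, 1172 higher and 1356 lower, and 44 by at least 2-fold. Without both GC-skewed libraries 4362 were called (2271 higher, 2091 lower), 2439 of them shared. RGS3, TLN1, HSPA5 and RPL35 lie in chromosome 9 windows whose genes were lower as a whole in this line. Of 54 named genes 47 kept the call in every setting.

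In LATS dKO cells ANKRD1 was higher than in WT by 3.85 on the log2 scale (adjusted p = 6.06e-18), CYR61 by 2.56 (adjusted p = 3.4e-16), CTGF by 2.53 (adjusted p = 6.37e-19) and AMOTL2 by 2.05 (adjusted p = 9.76e-10). TNNC1, the calcium-binding troponin of slow and cardiac muscle, rose from 1.07 ± 0.05 to 26.4 ± 1.08 FPKM on 1 kPa (3.54, adjusted p = 6.18e-16). The secreted PROK1 rose from 0.0779 ± 0.0155 to 10.0 ± 0.749 and the fibrillar collagen COL3A1 from 0.146 ± 0.0231 to 10.2 ± 1.17. EMC10 (ENSG00000161671.16, chromosome 19, 50979657 to 50994127), a subunit of the membrane protein insertion complex of the endoplasmic reticulum, fell from 26.8 ± 8.85 to 0.085 ± 0.0246 FPKM on 1 kPa and from 23.2 ± 0.44 to 0.0797 ± 0.00914 on 40 kPa (-4.56, adjusted p = 2.29e-12). PLTP, the phospholipid transfer protein, fell from 10.1 ± 0.606 to 0.483 ± 0.13 FPKM on 1 kPa (-2.97). LGR5, a Wnt-associated stem cell receptor, fell from 6.83 ± 0.343 to 0.385 ± 0.0666 (-2.27). EDIL3, COL12A1, OLFML1, NRG1 and GPRC5A were further named as higher (3.13 to 2.603) and RAMP1, CGA, ETV4, DMRT3, ETV5, BOC and RYR2 as lower (-2.44 to -1.94).

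Of 20 signature members 15 were higher in LATS dKO, FOXF2 lower and 4 not called (18 and 1 when adjusted over the list alone; camera adjusted p = 8.61e-12). All 6 epithelial markers tested were higher, KRT8 going from 141.1 ± 5.97 to 474.2 ± 19.2 FPKM on 1 kPa (6 when adjusted over the list alone; camera adjusted p = 7.77e-06). Of 35 adhesion genes 16 were higher, among them TNS3, ITGB8, ITGA1 and CAV1, and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.000795). Of 25 SRF and MRTF targets 14 were higher, TPM1 going from 41.4 ± 5.5 to 219.1 ± 9.22 FPKM on 1 kPa beside CNN2, FHL2 and FLNA, and 2 lower (14 and 5 when adjusted over the list alone; camera adjusted p = 0.00124). These 4 lists held with an estimated correlation, and the following did not. Of 33 Hippo pathway genes 13 were higher, such as TEAD1, WWC2, AMOT and TEAD4, and 5 lower (17 and 5 when adjusted over the list alone; camera adjusted p = 0.0135, and adjusted p = 0.121 with an estimated correlation). Of 35 matrix proteins 13 were higher, COL3A1, COL12A1, COL5A2 and COL4A6 among them, and 6 lower (13 and 8 when adjusted over the list alone; camera adjusted p = 0.0135, and adjusted p = 0.166 with an estimated correlation). Of 6 fibroblast markers COL3A1, LUM and S100A4 were higher and MMP2 lower, also when adjusted over the list alone (camera adjusted p = 0.0148, and adjusted p = 0.131 with an estimated correlation). Wnt targets had 5 lower of 11, LGR5, LEF1, APCDD1 and AXIN2 among them, also when adjusted over the list alone (camera adjusted p = 0.0135, and adjusted p = 0.131 with an estimated correlation), a call that was lost without both GC-skewed libraries. Notch targets had 5 lower of 8, such as HES5, HEY1, HEY2 and HES1 (5 lower and 1 higher when adjusted over the list alone; camera adjusted p = 0.0135, and adjusted p = 0.374 with an estimated correlation), a call also lost with GC correction.

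For LATS dKO against WT 5364 genes were called, 2539 higher and 2825 lower, and 238 by at least 2-fold. There were 6724 called (3234 higher, 3490 lower) and 5149 shared without both GC-skewed libraries. AMOT, COL4A6, FLNA and RAP2C (0.62, adjusted p = 4.68e-05) lie in windows of the long arm of chromosome X whose genes were higher as a whole in this line. Of 64 named genes 62 kept the call in every setting.

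In YAP/TAZ dKO cells CTGF fell by 3.44 on the log2 scale against WT (adjusted p = 2.5e-21). It stood at 0.23 ± 0.0278 FPKM on 1 kPa and 0.222 ± 0.064 on 40 kPa. AMOTL2 had -2.64 (adjusted p = 1.22e-11), in a chromosome 3 window with a median of -0.65, CYR61 -1.98 (adjusted p = 7.42e-15) and ANKRD1 -1.53 (adjusted p = 1.35e-12). The neurofilament light chain gene NEFL was higher by 4.85, going from 17.4 ± 0.335 to 534.6 ± 33.1 FPKM on 1 kPa and from 15.0 ± 0.439 to 456.6 ± 0.685 on 40 kPa (adjusted p = 4.18e-21). POU3F2, a neural transcription factor, rose from 0.31 ± 0.0577 to 12.4 ± 0.375 on 1 kPa (3.41). The cell cycle regulator CCND1 rose from 15.6 ± 1.25 to 140.4 ± 8.42 FPKM on 1 kPa, and DDIT4 from 10.3 ± 1.11 to 59.8 ± 2.43. The keratin KRT19 (-4.09), the adaptor subunit AP1M2 (-4.08), BST2 (-3.95) and the amino acid transporter SLC7A5 (681.4 ± 23.2 to 70.2 ± 3.83 FPKM on 1 kPa; -3.60) were among the largest falls. PUDP, CTNNA3, ENPP2 and MXD4 were further named as higher (3.25 to 2.65) and LGALS3, VAMP8, ANXA1, TAF7L and PTRF as lower (-3.57 to -3.08). RFX7 and TEX9, neighbouring genes of chromosome 15, stood at 6.38 ± 0.264 and 5.50 ± 0.612 FPKM in YAP/TAZ dKO on 1 kPa and at 6.64 and 5.41 on 40 kPa. In the 18 libraries of the other 3 genotypes RFX7 was listed at 0 in 15 and stood at up to 0.0101 FPKM. TEX9 was listed at 0 in 17 and stood at 0.0191 FPKM in the other. Whether the lines descend from the same WT cells is not given in the sources used here, so a difference from WT compares cell lines and not the targeted genes alone.

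Of 20 signature members 13 were lower in YAP/TAZ dKO, 3 higher (FOXF2, ASAP1 and GADD45A) and 4 not called, also when adjusted over the list alone (camera adjusted p = 0.00149, and adjusted p = 0.0523 with an estimated correlation). All 6 epithelial markers were lower, also when adjusted over the list alone, KRT8 (-2.50), KRT18 (-1.80) and OCLN (-0.72) among them (camera adjusted p = 9.94e-06). Of 35 adhesion genes 23 were lower, CAV1 (-2.67), CD44 (-2.36), CAV2 and ACTN1 (-0.89) among them, and 3 higher, also when adjusted over the list alone (camera adjusted p = 8.42e-05). These 2 lists held with an estimated correlation, and the following did not. Of 8 Notch targets 5 were higher, among them HEY1, going from 30.4 ± 2.88 to 74.6 ± 2.03 FPKM on 1 kPa, HES5, NOTCH3 and HEYL, also when adjusted over the list alone (camera adjusted p = 0.00308, and adjusted p = 0.323 with an estimated correlation). Of 24 cholesterol synthesis genes 14 were lower, such as IDI1, SC5D and FDPS, and 2 higher, such as SQLE (15 and 2 when adjusted over the list alone; camera adjusted p = 0.00701, and adjusted p = 0.206 with an estimated correlation). Of 32 ribosomal proteins 16 were higher, such as RPLP2 and RPL4, and 4 lower, such as RPS23, also when adjusted over the list alone (camera adjusted p = 0.0178, and adjusted p = 0.385 with an estimated correlation). Fibroblast markers had 5 lower of 6, VIM, MMP2, LUM and COL3A1 among them, also when adjusted over the list alone (camera adjusted p = 0.0357, and adjusted p = 0.206 with an estimated correlation). Of 17 interferon response genes 8 were lower, such as BST2, IFITM3, IFIT1 and IFITM2, and 2 higher, also when adjusted over the list alone (camera adjusted p = 0.0482, and adjusted p = 0.13 with an estimated correlation). The calls of fibroblast markers and interferon response genes were lost without both GC-skewed libraries, that of fibroblast markers also with GC correction.

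For YAP/TAZ dKO against WT 8008 genes were called, 3738 higher and 4270 lower, and 498 by at least 2-fold. There were 9699 called (4749 higher, 4950 lower) and 8007 shared without both GC-skewed libraries. WWTR1, AMOTL2, CCDC80 and RAP2B on chromosome 3, CAV1 and CAV2 on chromosome 7 and OCLN on chromosome 5 lie in windows whose genes were lower as a whole in this line. Of 66 named genes 61 kept the call in every setting.

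The genotype differences were also placed along the genome in 263 windows of 10 Mb with at least 20 genes each. A window was marked where the median log2 difference from WT of its genes, less that of all genes, went beyond the largest of 200 shuffles of the genes. There were 11 such windows in RAP2 tKO, all lower. LATS dKO had 14, 10 higher and 4 lower, and YAP/TAZ dKO had 20, 1 higher and 19 lower. They held 339 of the called genes in RAP2 tKO (13.4%, with 3.8% of the genes tested). In LATS dKO they held 458 (8.5%, with 4.2%) and 699 in YAP/TAZ dKO (8.7%, with 5.6%). The largest median in RAP2 tKO was -0.51 on chromosome 9 (110000001 to 120000000), in LATS dKO 0.58 on chromosome X (110000001 to 120000000) and in YAP/TAZ dKO -0.82 on chromosome 3 (140000001 to 150000000).

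**Figure D4:**
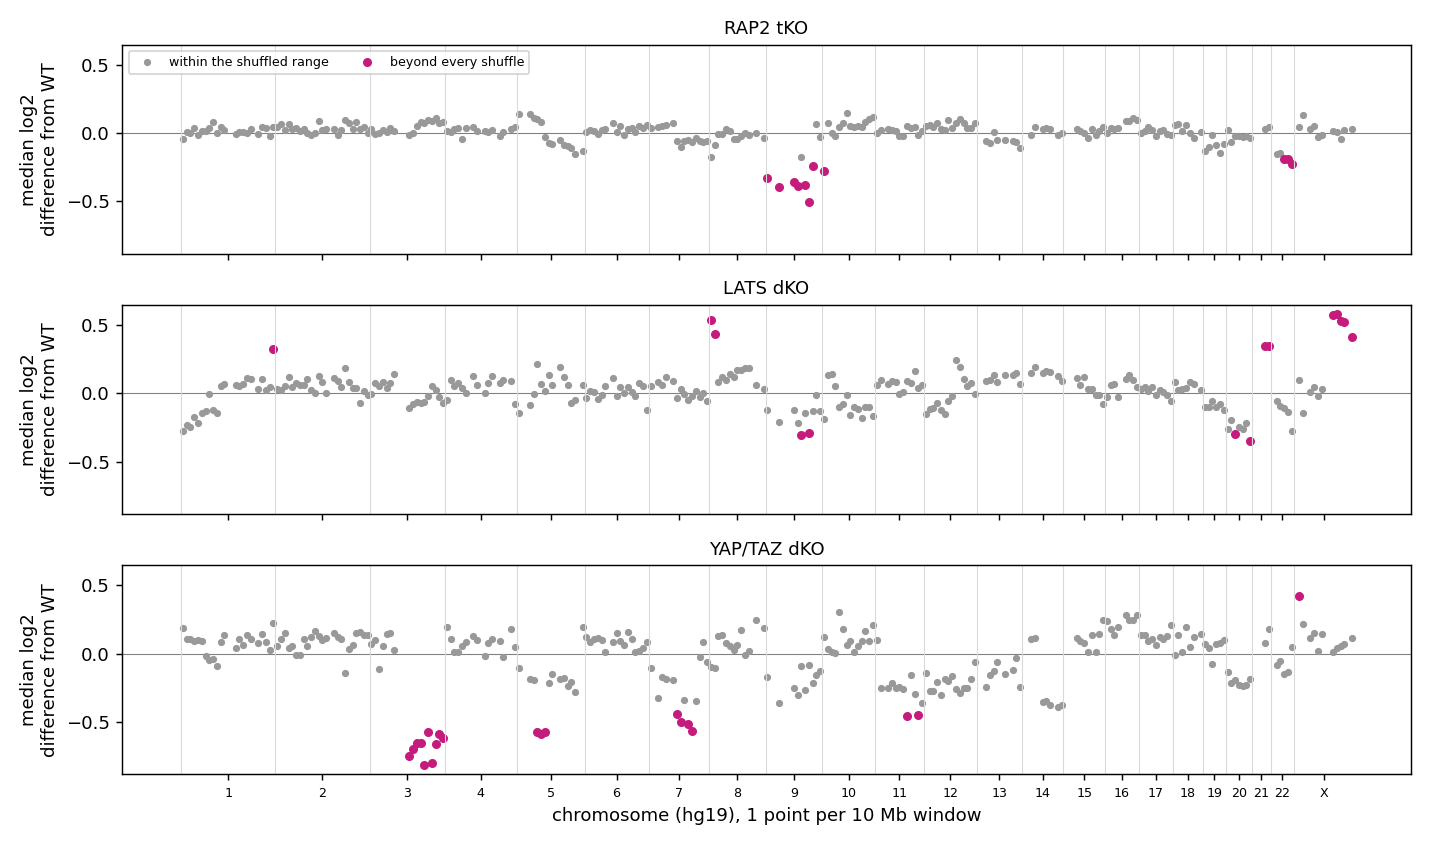
Median log2 difference from WT of the genes in each 10 Mb window along the hg19 chromosomes, 1 panel per knockout line, with windows beyond every shuffle in magenta. They number 11 in RAP2 tKO, 14 in LATS dKO and 20 in YAP/TAZ dKO.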

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

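Of the tests given here, those of GC content bias, of the depth of RAP2 tKO on 40 kPa replicate 3, of a wrong label, of chance placement of genes, of a GC content trend in the windows and of the pseudocount were chosen only after the result was seen.

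For 29 gene responses the interaction test found that the change with stiffness differed between a knockout line and WT. In RAP2 tKO the differences (log2 change in the line minus that in WT) were 0.92 for ANKRD1, 0.55 for FSTL1, -1.75 for EGR1, -1.22 for ETV4, -0.99 for CTGF, -0.81 for NAB2 and -0.66 for KRT18. In LATS dKO they were 0.47 for PDE7A, -1.44 for CTGF, -1.17 for AJUBA, -0.96 for ANKRD1, -0.86 for KRT18, -0.83 for CYR61 and -0.64 for KRT8. They were positive in YAP/TAZ dKO for IGFBP5 (1.09), DDB2 (1.08), SEC31B (0.98), DDIT4 (0.80), STAT2 (0.74) and HES5 (0.71). They were negative there for AMOTL2 (-1.66), CTGF (-1.65), ANKRD1 (-1.45), ANXA1 (-1.44), TNFRSF12A (-1.09), CYR61 (-1.08), KRT8 (-0.95), KRT18 (-0.86) and TAGLN2 (-0.47). MTATP6P1 and MTCO1P12, nuclear copies of mitochondrial genes that no comparison used, had a mean of 7151 and 6978 FPKM over the 17 libraries with a value (5873 to 8079 and 6094 to 7970) and were listed at 0 in the other 7. Those are WT on 1 kPa replicate 2, WT on 40 kPa replicates 2 and 3, RAP2 tKO on 40 kPa replicate 3 and YAP/TAZ dKO on 1 kPa replicates 1 to 3, and the files mark both genes there, among 22 entries each, as having too much data to estimate. A 0 is thus no level, although it falls in 3 of 3 YAP/TAZ dKO libraries on 1 kPa and 0 of 3 on 40 kPa.

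The stiffness responses of ANKRD1 and CTGF in RAP2 tKO departed from those of WT in opposite directions. For ANKRD1 the interaction of 0.92 (adjusted p = 0.00797) came to 0.41 with a pseudocount of 0.1 (adjusted p = 0.751; 0.00103 to 0.751 over all alternatives run), so that compression of the low level in WT by the pseudocount may account for much of it. For CTGF the same change of pseudocount gave -1.11 (adjusted p = 0.00309; 3.7e-07 to 0.00309 over all alternatives run), which argues against that explanation. Without RAP2 tKO on 40 kPa replicate 3 the interactions were 0.83 for ANKRD1 (adjusted p = 0.0194) and -0.96 for CTGF (adjusted p = 6.55e-06), so this library was not the whole source of either. A smaller response of CTGF on the log2 scale after loss of RAP2 remains a hypothesis, beside untested ones such as a limit to the response of a gene that is already high on 1 kPa.

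RAP2 tKO on 40 kPa replicate 3 and LATS dKO on 40 kPa replicate 1 deviated from their groups, and a GC content bias of both libraries has the values it needs: the rank correlation with GC content across genes was -0.598 and -0.567, against at most 0.333 in size in the 18 libraries of the other 6 groups. Their group mates had 0.382 to 0.536, tied to them by centring on a mean of 3, but for the change from the 1 kPa mean of the genotype the correlation was -0.593 and -0.57 against -0.09 to 0.153 in the mates, while the step at which such a bias may have arisen stays open and no biological explanation was tested. Lower depth is argued against, since the first library had 34.37 M fragments against a median of 33.85 M, and in the second, the smallest with 20.09 M, the correlation was -0.683 among the 5276 genes with the highest mean. A wrong genotype label is argued against, since on 200 genes that separate the genotypes on 1 kPa the lowest position of both between another genotype (0) and their own (1) was 0.773, that of RAP2 tKO on 40 kPa replicate 3 against LATS dKO, with 0.838 and 0.844 in its mates and at most 0.052 in LATS dKO on 40 kPa; against WT it had 0.775, its mates 0.698 and 0.7 (below the bound of 0.75 set for the test) and WT on 40 kPa at most 0.408. An earlier test settles less on genotype: 2 of 2 lay nearest to a group of their own genotype after GC correction (0.546 against 0.549 for its own group in RAP2 tKO, which as deposited lay nearest to LATS dKO on 40 kPa, and 0.523 against 0.58 in LATS dKO) with scores of -0.268 and -0.267 outside those of their lines on 1 kPa, but beside those of both lines on 40 kPa (-0.281 to -0.267 and -0.267 to -0.249), and it had replaced, after its result was seen, a form asking for the own group to be nearest, passed by 0 of both and by only 10 of all 24 libraries (14 as deposited).

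Genotype effects gathered in windows of 10 Mb, 11 lower in RAP2 tKO (7 of them on chromosome 9, 3 on 22 and 1 on 10), 14 in LATS dKO (higher were 5 on X, 2 each on 8 and 21 and 1 on 1, lower 2 each on 9 and 20) and 20 in YAP/TAZ dKO (lower were 10 on 3, 4 on 7, 3 on 5 and 2 on 11, higher 1 on X). Chance placement of genes is argued against, since these 11, 14 and 20 windows went beyond the largest median of 200 shuffles (0.179, 0.289 and 0.402 in size). A GC content trend is argued against as the whole cause, since 9 of the 11, 12 of the 14 and 20 of the 20 windows were also beyond the shuffles after correction (11, 12 and 21 in all), while 2 of the 3 on chromosome 22 in RAP2 tKO went from -0.188 to -0.171 and from -0.225 to -0.158 (limit 0.179, then 0.178) and both on chromosome 20 in LATS dKO from -0.3 to -0.283 and from -0.348 to -0.267 (limit 0.289, then 0.303), so that they fell short of the limit with most of the median left. A regional dosage difference of the line, such as a gained or lost stretch of chromosome, has the values it needs: in windows chosen on 1 kPa, at least 84.2% (RAP2 tKO), 79.3% (LATS dKO) and 75.6% (YAP/TAZ dKO, close to the bound set for the test) of genes in each of 3 classes of expression went the way of their window on 40 kPa. Such a difference may come from the history of a clone and not from the targeted genes, and other regional mechanisms stay open, as DNA was not analysed here.

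Other splits of the libraries were also fitted. For the stiffness contrasts the 10 splits are too few for a share under 0.05, with 156 calls in WT, 612 in RAP2 tKO, 112 in LATS dKO and 55 in YAP/TAZ dKO against at most 1, 1, 2 and 2 in the other splits. For the interactions chance was not excluded. Splits with at least the real number of calls were 9 of 100 in RAP2 tKO (real 8, at most 1240). They were 6 in LATS dKO (real 10, at most 345) and 2 in YAP/TAZ dKO (real 62, at most 140). The highest counts came from splits that keep the groups whole and turn the stiffness labels in 1 genotype. The other splits break the stiffness response itself, so they do not test equal responses. For the genotype effects 1 of 100 splits was as large in each line. Calls were 2528, 5364 and 8008 against at most 108, 1971 and 3568. Libraries and not clones were split, so the effect may be the line's.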

How the results depend on the processing

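Alternatives chosen only after the result was seen were the fits without both GC-skewed libraries and with GC correction, and for the score and the shared calls those beyond the ones fixed in advance, kept whatever they gave. The directions of the 334 named gene results held under the alternatives run, with 2 exceptions. FOXF2, stiffness in RAP2 triple knockout, came to 0.038 after GC correction, against -0.299 as reported. CTGF, stiffness in YAP TAZ double knockout, which was not called, lay between -0.045 and 0.03 when 1 library was left out, turning without replicate 3 on 40 kPa. Of the 334 results 327 were called, and the call was lost for 100 with the compared groups fitted alone, 35 without a filter, 28 with GC correction, FOXF2 included, 13 with a pseudocount of 0.1, 11 with scaling, 7 without both GC-skewed libraries and 2 with array weights, and for 5 of the 302 calls tested at a minimum of 5 FPKM. It was gained for 3 with array weights, 3 without both GC-skewed libraries and 1 with GC correction. Of the 78 list calls 51 were lost with an estimated correlation, 12 without both GC-skewed libraries, 8 with GC correction, 5 with a pseudocount of 0.1, 4 without a filter and 1 with scaling. Fry, a different test, did not call 19. These were adhesion, cholesterol, G2/M, Hippo and TGF-beta genes for stiffness in WT, adhesion and G2/M in RAP2 tKO, immediate-early and TGF-beta in LATS dKO and histones and ribosomal proteins in YAP/TAZ dKO. In the interactions they were immediate-early, Notch and ribosomal genes in RAP2 tKO, the same and G2/M in YAP/TAZ dKO and ribosomal proteins in LATS dKO. The signature in YAP/TAZ dKO against WT had adjusted p = 0.0523 with an estimated correlation (2e-15 to 0.0523 over the alternatives, the lowest being that of fry). The cause was not tested, except that fitting the compared groups alone leaves fewer libraries to estimate the spread. Alternatives that need counts were not run. Depth limits genes of low FPKM most.

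With a pseudocount of 0.1 the RAP2 tKO interaction had 3 calls, and the scores were 0.397 in RAP2 tKO and 0.155 in LATS dKO. Without a filter, stiffness in RAP2 triple knockout had 387 calls, the RAP2 and LATS interactions had 13 and 22, and the scores were 0.321 and 0.113. Scaling gave 49 calls for stiffness in LATS double knockout, 20 for its interaction and 11 shared calls, with scores of 0.303 and 0.088. With the compared groups fitted alone, stiffness had 45 calls in WT, 8 in RAP2 tKO and 2 in LATS dKO, the interactions had 4, 5 and 273, and the shared calls were 2, 1 and 1. The scores were then 0.454, 0.34 and, reversed in YAP/TAZ dKO, -0.024.

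Array weights were 0.07 for RAP2 tKO on 40 kPa replicate 3 and 0.12, 0.41 and 4.8 for LATS dKO on 40 kPa replicates 1, 2 and 3. They led to 1108 calls for stiffness in WT, 1052 for stiffness in RAP2 triple knockout, 2088 for stiffness in LATS double knockout and 532 for stiffness in YAP TAZ double knockout. Calls for the stiffness by genotype interaction RAP2 triple knockout were 28, for the stiffness by genotype interaction LATS double knockout 552 and for the stiffness by genotype interaction YAP TAZ double knockout 469. The genotype effect RAP2 triple knockout had 4537. The overlap of stiffness calls RAP2 triple knockout and WT was 403, the overlap of stiffness calls LATS double knockout and WT 244, and that of YAP/TAZ dKO 69, with scores of 0.238 and 0.088. Without both GC-skewed libraries, stiffness had 1006 calls in WT, 472 in LATS dKO and 391 in YAP/TAZ dKO, the interactions 20, 211 and 413, and RAP2 tKO against WT 4362. The signature in LATS dKO then had adjusted p = 0.0251 for stiffness (0.0251 to 0.46 over the alternatives), the shared calls were 338, 85 and 54, and the scores 0.219 and 0.082. GC correction gave 439, 968 and 113 calls for stiffness in WT, RAP2 tKO and YAP/TAZ dKO, 38 and 148 for the LATS and YAP/TAZ interactions, 230 shared calls in RAP2 tKO and scores of 0.249 and 0.089. At an unadjusted p below 0.05 in the knockout line the shared calls were 65 in LATS dKO and 26 in YAP/TAZ dKO. With the 50 genes of smallest p in WT the scores were 0.558 and 0.177.

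Leaving out 1 library gave 46 to 104 calls for stiffness in WT: 77 and 46 without replicates 2 and 3 on 1 kPa, and 68, 63 and 80 without replicates 1, 2 and 3 on 40 kPa. For stiffness in RAP2 triple knockout it gave 258 to 1141: 258, 312 and 265 without replicates 1, 2 and 3 on 1 kPa, and 1141 and 340 without replicates 1 and 3 on 40 kPa. For stiffness in LATS double knockout it gave 17 to 255: 22, 17 and 38 without those on 1 kPa and 33, 60 and 255 without those on 40 kPa. For stiffness in YAP TAZ double knockout it gave 29 to 43: 32 and 31 without replicates 1 and 2 on 1 kPa, and 36 and 29 without replicates 1 and 2 on 40 kPa. The interactions had 5 to 12 calls in RAP2 tKO (5 without each of WT on 1 kPa replicates 2 and 3, WT on 40 kPa replicates 1 and 3 and RAP2 tKO on 1 kPa replicate 1), 7 to 63 in LATS dKO (63 without its replicate 3 on 40 kPa) and 40 to 53 in YAP/TAZ dKO (40 without WT on 1 kPa replicate 3 or YAP/TAZ dKO on 40 kPa replicate 3, 41 without WT on 40 kPa replicate 2 or 3). The genotype effects had 2077 to 2957, 4818 to 5445 and 7511 to 7616.

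The replicate block gave 57 calls for stiffness in LATS double knockout and a score of 0.373 in RAP2 tKO. The other counts of calls moved by less than 1.5 times, and 21 of the 327 gene calls and 1 of the 78 list calls, that of Notch targets in the YAP/TAZ dKO interaction, were lost. Libraries with the same replicate number did not deviate together (84 pairs, median correlation -0.001, -0.247 to 0.149), and 7 of 24 libraries correlated best with their own number, so the number pairs no samples.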

Other observations

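The tests of correlation between knockout lines were chosen only after the result was seen.

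Genes of the pathway itself differed between the lines. LATS2, itself a YAP and TAZ target, rose by 0.49 in RAP2 tKO (adjusted p = 0.0219) and fell by 0.83 in YAP/TAZ dKO (adjusted p = 6.61e-05), on the log2 scale over both stiffnesses (limma). RAP2B fell by 0.31 in YAP/TAZ dKO (adjusted p = 2.05e-05), in a chromosome 3 window with a median of -0.57. Of other signature members, MYOF was higher by 0.49 in RAP2 tKO and 1.20 in LATS dKO and fell by 1.17 in YAP/TAZ dKO. CRIM1 was higher by 0.52 and 1.12 and fell by 0.45, and PTPN14 was higher by 0.32 and 0.68 and fell by 0.28.

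Fatty acid synthesis (lowest adjusted p over the 10 contrasts 0.097), hypoxia and glycolysis genes (0.0911), genes of G1/S (0.218) and oxidative phosphorylation (0.154) were not called in any contrast. The lists with too few genes tested hold values only. Of neuronal markers UCHL1 stood at a mean of 798.9 FPKM in WT on 1 kPa and 832.1 in YAP/TAZ dKO, TUBB3 at 7.72 and 14.2, and GAP43 at 2.73 and 1.32. The immune marker CD68 stood at 5.46 FPKM in WT on 1 kPa and the endothelial marker ESAM at 0.743. The 13 genes of the mitochondrial genome were listed at 0.

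If knockout of RAP2 or of LATS moves the same genes, effects measured on separate libraries would correlate. Across 15828 genes, which are not independent, RAP2 tKO and LATS dKO had r = 0.09 and 0.192 in the pairings of 1 with 40 kPa and of 40 with 1 kPa, which leaves it undecided. For RAP2 tKO and YAP/TAZ dKO the values were 0.006 and -0.012, so opposite effects over all genes were not seen. They were not excluded, since both lines were set against the same WT line and an offset of WT would raise each r. For LATS dKO and YAP/TAZ dKO opposite effects stayed undecided (-0.071 and -0.063). Outside the chromosome windows with gathered effects the pairings gave 0.082 and 0.187 for RAP2 tKO with LATS dKO, -0.003 and -0.01 for RAP2 tKO with YAP/TAZ dKO, and -0.081 and -0.069 for LATS dKO with YAP/TAZ dKO.

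A further hypothesis was that loss of RAP2 or LATS moves the WT stiffness genes on the soft gel toward their state on the stiff gel. The 156 genes of smallest p were chosen anew without 1 WT library on 1 kPa, against which each line was then set. The mean signed log2 difference from that library was 0.19 to 0.22 in RAP2 tKO on 1 kPa and 0.41 to 0.45 in LATS dKO on 1 kPa, with 0.39 to 0.42 in WT on 40 kPa. The other WT libraries on 1 kPa stood at -0.15 to -0.13. Both are consistent with such a shift, which remains a hypothesis because the lines also differ in other ways. The difference in YAP/TAZ dKO on 1 kPa was -0.10 to -0.04, with no net shift seen.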
